A study of Solanum lycopersicum with 36 samples.

How the data were processed

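Poly(A) RNA from leaves of tomato (Solanum lycopersicum, cultivar Micro-Tom) was sequenced on a DNBSEQ platform, per the labels. Plants were about a month old and the third and the fourth leaf were sampled, per the labels' protocols. The 36 libraries fall into 12 groups of 3, from 2 experiments run independently: SGT2ox with its wild type and SGT1ami with its wild type, each at 0, 3 and 24 h. The groups were taken from the sample titles. The temperature of a library is not among its labels. Samples were taken from control and from cold-treated plants, per the labels' protocols.

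The submitters' processing notes name Trimmomatic, STAR, featureCounts and DESeq2, with no versions, roles or order. The genome build and annotation are not given in the sources used here. The deposited table holds 29285 genes by 36 libraries as a signal made by the authors, gene counts divided by a size factor per library. This was read from the values: in every library 100% of the values were whole multiples of the smallest value above 0, within 0.01 of a whole number of reads. The factors equal DESeq2's median-ratio factors over all 36 libraries (ratio 1) and range from 0.779 to 1.311. The reads so recovered from the deposited signal number 36602841 to 43742623 per library. Of the values of 2 to 11 reads, 78.8% were even, so both mates of a fragment were mostly counted and the number of independent fragments is lower than the number of reads. Whether strand was used in counting is not given in the sources used here, so overlapping genes cannot be separated from each other. Near-identical copies may share reads as well, and how such reads were counted was not examined.

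Size factors assume that most genes do not change. Where many genes change, as between 0 h and 24 h, they fix the median change near 0, and the balance of rises and falls follows from that choice. Normalisation by library totals was therefore added after the data were seen.

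Tests were made with limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(value + 1), so a fold change understates the change of low genes. Each experiment was fitted on its own, as 18 libraries in 6 groups with 12 residual degrees of freedom, so that all groups share an estimate of the spread. Genes with a value of at least 10 in at least 3 of the 18 libraries were tested, 22399 in the SGT2ox experiment and 22286 in the SGT1ami experiment. P-values were adjusted by the Benjamini-Hochberg method within each comparison and called at 0.05. The 18 comparisons were each later time against 0 h in each genotype, each line against its wild type at each time, and the difference of the changes from 0 h between line and wild type. Fold changes and SE are those of the fit, and levels are means ± SD of the deposited values of 3 libraries. Overlaps between comparisons that share no library were tested with Fisher's exact test beside the number that independent lists would share. Wild types of the 2 experiments were compared in a fit of all 36 libraries.

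The design, the tests, the alternatives, the rule for named genes and 27 gene lists were fixed before the data were examined. The rule named the sterol glycosyltransferase genes, the 6 rises and 6 falls common to both wild types ranked by the smaller of both changes, and the 5 highest and 5 lowest called genes of each line comparison and of each difference of changes, all with a mean value of at least 50 over all 36 libraries, so that a named gene can lie below 50 in the groups compared. It also asked for a gene description. None of the 29285 identifiers matched the 41476 entries of the reference gene table (0 matches), so no gene list had a member, no gene list test was run, and the condition on descriptions could not be applied. At most 2 rises and 2 falls chosen by the rule are printed per comparison, and the identifiers noted for SGT1 and SGT2 in all comparisons. Those 2 identifiers were written down from memory at the same stage, and no table used here pairs them with the names. Other preset lists held such remembered identifiers too, which were not used.

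On simulated counts made from the means, size factors and dispersions of these libraries, the test recovered 7.7% of genes changed 1.1-fold, 57.9% at 1.25-fold, 76.3% at 1.5-fold, 87.5% at 2-fold and 95% at 4-fold for SGT2ox against wild type at 0 h (21915 genes). For SGT1ami against wild type at 0 h (21861 genes) the shares were 17.5%, 52.5%, 67.6%, 89.5% and 94.9%. For the difference of the changes to 3 h in the SGT2ox experiment (21908 genes) they were 0%, 25.6%, 55%, 79.5% and 92.5%, and for that to 24 h in the SGT1ami experiment (21863 genes) 5%, 35.9%, 65%, 79.5% and 92.5%. Between 3 and 8 unchanged genes were called in each simulation. Only 40 genes were changed at each fold, far fewer than were called in the data, so the cut-off on the unadjusted p was stricter here. The shares and false calls therefore do not carry over to the real comparisons.

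The alternatives were TMM scaling of the recovered reads, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, a pseudocount of 8, no filter, a filter of 50, one fit of all 36 libraries, a fit of only the groups compared, a 2-fold threshold, the replicate number as a block, and each library left out in turn. On the recovered reads, 100% of which came out whole, edgeR called 6536, 3952 and 7590 genes between SGT2ox and wild type at 0, 3 and 24 h, and 5046, 6907 and 4858 between the libraries labelled SGT1ami and wild type. Scaling by library totals and leaving out the libraries labelled SGT1ami at 24 h were added after the data were seen.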

Results

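Leaf transcriptomes were collected from tomato plants of the dwarf cultivar Micro-Tom in 2 independent experiments. One experiment set the line SGT2ox beside its own wild type and the other set the line SGT1ami beside another wild type set. SGT1 and SGT2 are known from published work as sterol glycosyltransferases, enzymes that attach a sugar to membrane sterols. The suffix of SGT2ox is read here as overexpression and that of SGT1ami as an artificial microRNA against SGT1. Leaves were taken at 0, 3 and 24 h, with 3 libraries in each of 12 groups and 36 libraries in all. The study as a whole concerned cold tolerance and jasmonate signalling. Its protocol moved part of the plants to a cold chamber, but the sample labels carry a time and no temperature. No library was labelled as a control of the same hour, so a change from 0 h is called here a change with time.

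The libraries held between 36602841 and 43742623 recovered reads each, and between 23650 and 24345 genes had at least 1 read. Replicates lay close together, with a common biological coefficient of variation of 4.88% in the SGT2ox experiment and 3.79% in the SGT1ami experiment. In each of 36 replicate pairs the reads differed by more than sampling noise (mean chi-square per gene 2.66 to 7, or 1.33 to 3.5 if every fragment was counted as a pair of reads), so all 3 libraries of a group were kept. The labels call the triplicates biologically independent. The p-values below measure only the spread between these very similar libraries. The files do not pair the gene identifiers with gene names, so genes are given by identifier and their functions are not described.

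The first question was how the libraries grouped. Over 22945 expressed genes, the first principal component held 56.1% of the variance and set the 24 h libraries (scores of -186.1 to -129.6) apart from all libraries of 0 h and 3 h (scores of 49.3 to 105). The second and the third component held 13.5% and 11.7% and separated the experiments and the 0 h from the 3 h libraries. A few genes took more of the reads at 3 h in the SGT2ox experiment than elsewhere. The 100 most abundant genes held 33.3% ± 0.361 of the reads in its wild type and 32% ± 0.473 in SGT2ox at that time (mean ± SD, n = 3), against 19% to 27.5% in the libraries of the other groups.

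**Figure D1:**
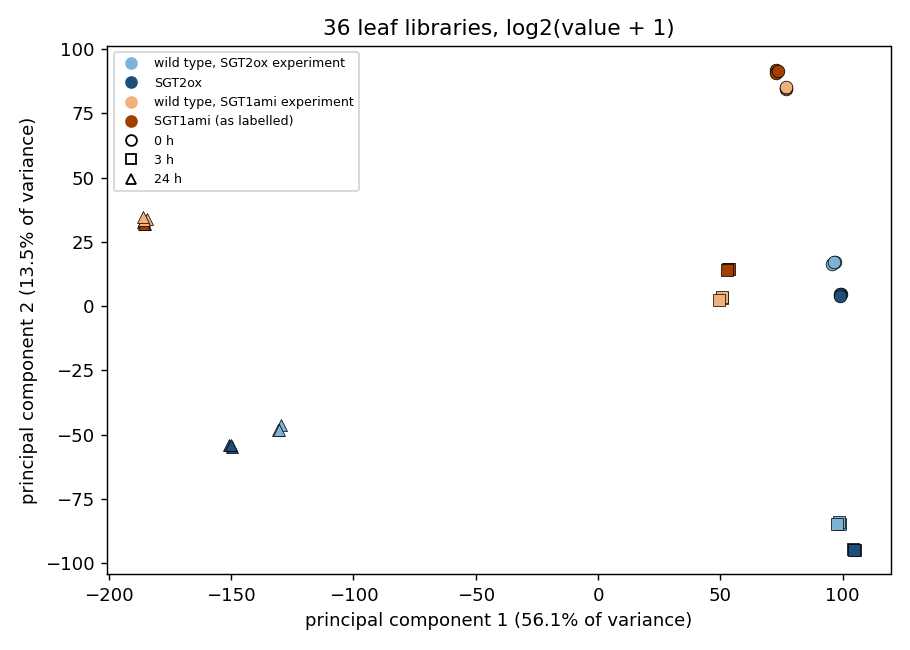
Scores of the 36 libraries on the first component (56.1% of variance, horizontal axis) and the second component (13.5%, vertical axis) of log2(value + 1), with color for genotype and experiment and marker shape for time. The 24 h libraries lie between -186.1 and -129.6 on the first component and the others between 49.3 and 105.

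The targeted genes were examined first, because they test the labels. Identifiers for SGT2 (Solyc09g061860) and SGT1 (Solyc06g007980) had been noted from memory of published tomato work and are paired with these names by no table used here. Solyc09g061860 reached 26660 ± 248 normalised reads in SGT2ox against 994.9 ± 59.4 in its wild type at 0 h, 54160 ± 512 against 1624 ± 22.1 at 3 h, and 44060 ± 467 against 1372 ± 18.8 at 24 h (mean ± SD, n = 3). These are 26.8-fold, 33.3-fold and 32.1-fold differences, with limma log2 fold changes of 4.74, 5.06 and 5 (SE 0.037 each) and adjusted p-values of 1.3e-32, 2.7e-33 and 3.5e-33. Among the 7430 tested genes with a mean of at least 1000 normalised reads over all 36 libraries, it had the largest increase in SGT2ox at each time. Over all 22399 tested genes it was number 24, 20 and 22 from the highest at 0, 3 and 24 h. In the same line Solyc06g007980 was 1.07-fold higher at 0 h (adjusted p = 0.076, limma), 1.14-fold higher at 3 h (adjusted p = 0.00046, limma) and 1.01-fold lower at 24 h (adjusted p = 0.81, limma).

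Solyc06g007980 stood at 2435 ± 69.7 in SGT1ami against 7845 ± 112 in its wild type at 0 h and at 2373 ± 95.1 against 5948 ± 198 at 3 h. It was 3.22-fold lower at 0 h (log2 fold change -1.69, SE 0.035, adjusted p = 4.2e-23, limma) and 2.51-fold lower at 3 h (log2 fold change -1.33, SE 0.035, adjusted p = 5.7e-21, limma). By rank it was number 3 and number 9 from the lowest among the 7430 abundant genes, and number 69 and number 269 among all 22286 tested genes. At 24 h the libraries labelled SGT1ami held 6173 ± 51.3 and the wild type 6685 ± 214, a 1.08-fold difference (log2 fold change -0.11, SE 0.035, adjusted p = 0.017, limma). That call ended without replicate 2 of the labelled line (-0.11), without replicate 1 of the wild type (-0.10), without replicate 2 of the wild type (-0.10), and when values were scaled by library totals (-0.02). The targeted gene therefore goes against the label at 24 h, and those 3 libraries are called the libraries labelled SGT1ami at 24 h throughout. Every direction drawn from them carries this doubt. Solyc09g061860 was 1.27-fold lower in SGT1ami at 0 h (adjusted p = 5.3e-09, limma) and 1.01-fold lower at 3 h (adjusted p = 0.75, limma). At 24 h it was 1.08-fold lower in the labelled libraries (log2 fold change -0.11, adjusted p = 0.016, limma). This call ended when only the groups compared were fitted (-0.11), without replicate 3 of the labelled line (-0.08), without replicate 3 of the wild type (-0.09), and with library totals (-0.02).

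**Figure D2:**
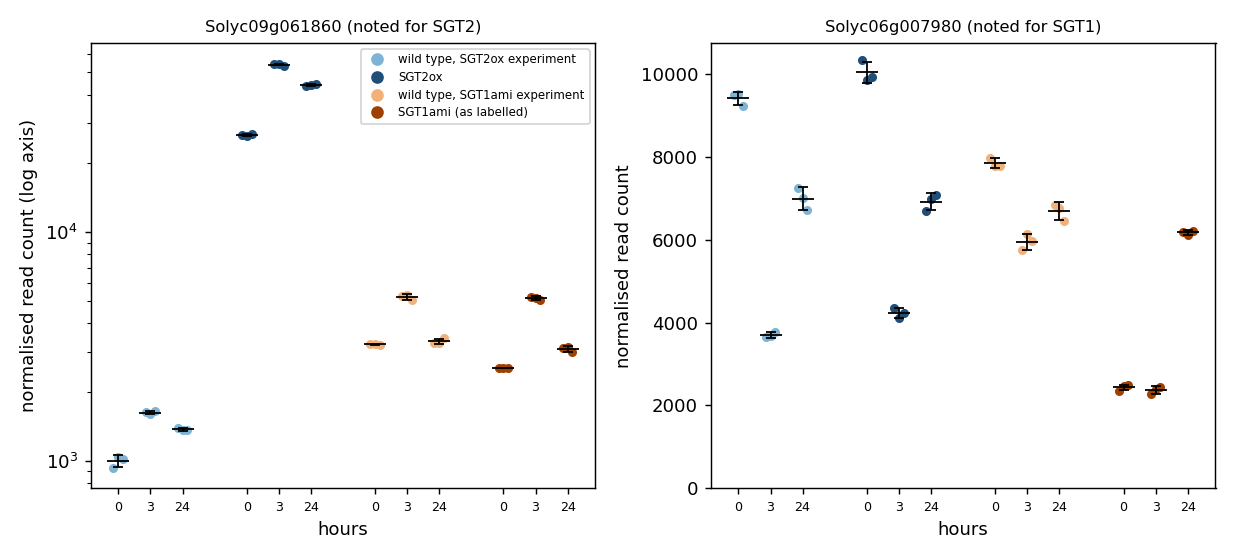
Normalised read counts of Solyc09g061860 (left, log axis) and Solyc06g007980 (right, linear axis) against hours for the 4 genotype sets; points are single libraries and bars the mean ± SD of 3. Solyc09g061860 lies at 26660 to 54160 in SGT2ox, and Solyc06g007980 lies at 2435 and 2373 in SGT1ami at 0 h and 3 h but at 6173 in the libraries labelled SGT1ami at 24 h.

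How did wild type leaves change with time? At 3 h the largest common rises among identifiers with a mean of at least 50 over all 36 libraries were those of Solyc00g500083, from 7.79 ± 5.56 to 1295 ± 288 in the SGT2ox experiment and from 2.38 ± 2.4 to 379 ± 82 in the SGT1ami experiment, and of Solyc00g500039, from 9.6 ± 3.71 to 1339 ± 272 and from 2.92 ± 1.67 to 416.3 ± 81.4. Both identifiers had close levels, with the same lowest library value at 0 h in SGT2ox (7.823) and the same highest at 0 h in its wild type (12.14). They may share reads and not be separate rises, which was not tested. Solyc01g096790 fell from 248.4 ± 33.2 to 3.25 ± 3.05 and from 74.1 ± 9.73 to 1.29 ± 1.12. Solyc12g009880.1 fell from 724.4 ± 49.3 to 43.8 ± 18.8 and from 674.8 ± 21.7 to 35.7 ± 5.33. Solyc06g007980 was also 2.54-fold lower at 3 h in the wild type of SGT2ox (adjusted p = 1.9e-21, limma) and 1.32-fold lower in that of SGT1ami (adjusted p = 4.9e-11, limma), and Solyc09g061860 was 1.63-fold and 1.61-fold higher (adjusted p = 2e-15 and 7.7e-17, limma).

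At 24 h genes that were silent at 0 h had become abundant. Solyc09g066400 rose from 2.08 ± 1.93 to 8170 ± 175 in the SGT2ox experiment and from 0.525 ± 0.909 to 3974 ± 191 in the SGT1ami experiment. Solyc09g075700.1 was at 0 in all 6 wild type libraries of 0 h and stood at 1359 ± 24.7 and 4060 ± 90 at 24 h. Solyc03g098480.1 went the other way, from 135.2 ± 12.5 and 107.4 ± 12.2 to 0 in all 6 libraries, and Solyc07g150120 fell from 227.9 ± 13.8 to 2.16 ± 2.16 and from 96.05 ± 2.52 to 0. In the wild type of SGT1ami Solyc09g061860 did not pass the test at 24 h (log2 fold change 0.04, adjusted p = 0.22, limma), and with library totals the value was -0.58.

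In the wild type of SGT2ox, 14841 of 22399 genes passed an adjusted p of 0.05 at 3 h (7830 higher, 7011 lower) and 17713 at 24 h (8847 higher, 8866 lower). In the wild type of SGT1ami, 13974 of 22286 passed at 3 h (6897 higher, 7077 lower) and 18355 at 24 h (9484 higher, 8871 lower). A change of at least 2-fold was found for 5174 and 8730 genes in the first wild type and for 3708 and 9772 in the second. The balance of rises and falls rests on the scaling. With library totals in place of the deposited size factors the median gene fell by 0.45 at 3 h and 0.28 at 24 h on the log2 scale in the wild type of SGT2ox, and by 0.24 and 0.58 in that of SGT1ami. The genes called with that scaling split into 3849 higher and 13275 lower, 6880 and 11297, 4705 and 10663, and 5798 and 13453.

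The responses of both wild types were shared in part. By a test of the difference itself, the change from 0 h differed between the wild types for 11860 genes at 3 h (3659 at least 2-fold) and 12011 at 24 h (4181). At 3 h 8473 of the 21851 genes tested in both experiments were called in the same direction and 2141 in opposite directions. At 24 h these numbers were 14092 and 1321. Independent lists would share 2420 rises and 2232 falls at 3 h, where 4531 and 3942 were found (Fisher's exact odds ratios 7.24 and 5.04), and 3698 and 3514 at 24 h, where 7223 and 6869 were found (odds ratios 26.3 and 21.4). Across genes, which are not independent replicates, Pearson's r was 0.58 at 3 h and 0.83 at 24 h, and Spearman's rho 0.54 and 0.82. At least 2-fold in both experiments and in the same direction were 1157 rises and 739 falls at 3 h and 3521 rises and 2896 falls at 24 h.

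**Figure D3:**
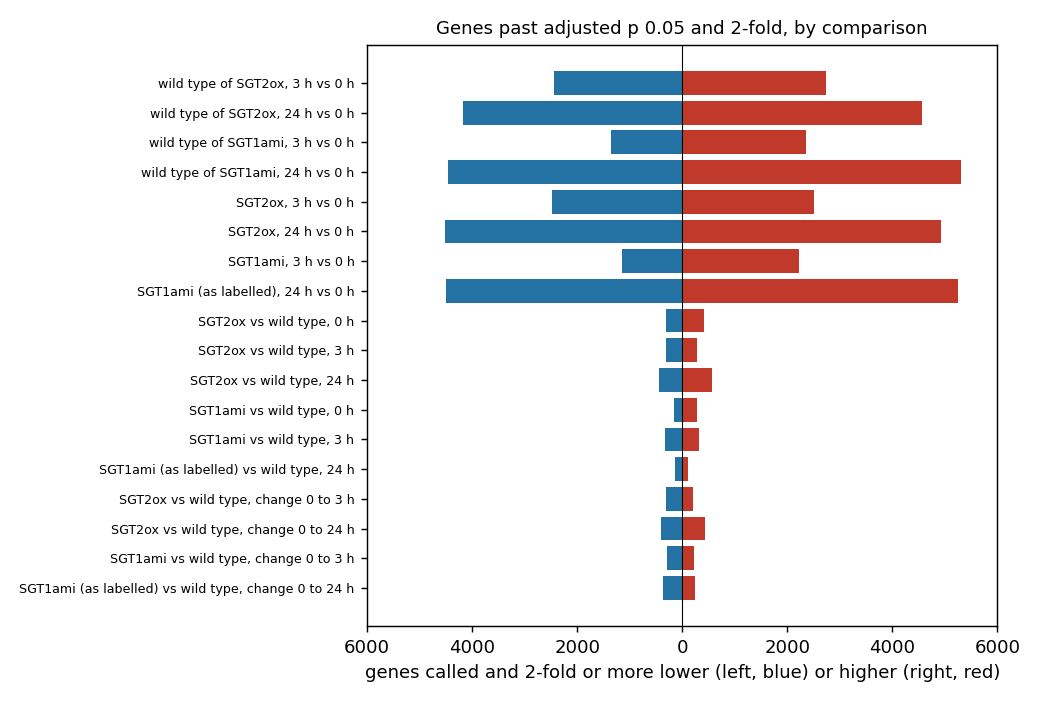
Genes past an adjusted p of 0.05 and changed at least 2-fold in each of 18 comparisons, with higher genes to the right and lower genes to the left of 0. Changes with time reach 9772 genes, and differences between a line and its wild type stay between 254 and 1011 genes.

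Both lines changed with time much as their wild types did. Solyc09g066400 rose to 7534 ± 342 in SGT2ox and to 4340 ± 85.5 in the libraries labelled SGT1ami at 24 h, and Solyc03g098480.1 fell to 0 in both. In SGT2ox 14519 genes changed at 3 h (7447 higher, 7072 lower) and 18164 at 24 h (9024 higher, 9140 lower). In SGT1ami 13853 changed at 3 h (6787 higher, 7066 lower), and between the SGT1ami libraries of 0 h and those labelled SGT1ami at 24 h 18448 genes differed (9506 higher, 8942 lower). With library totals the median gene fell by 0.33 and 0.22 in SGT2ox and by 0.21 and 0.50 in the SGT1ami set. The genes called with that scaling split into 4306 higher and 11908 lower at 3 h and 7623 and 10812 at 24 h in SGT2ox, 4881 and 10234 at 3 h in SGT1ami, and 6136 and 13020 for the libraries labelled SGT1ami at 24 h. Across genes the change of the line followed that of its own wild type with r of 0.89 at 3 h and 0.95 at 24 h in the SGT2ox experiment and 0.85 and 0.95 in the SGT1ami experiment, the last with the labelled 24 h libraries. Solyc09g061860 rose 1.21-fold between SGT1ami at 0 h and the libraries labelled SGT1ami at 24 h (log2 fold change 0.27, adjusted p = 1.5e-08, limma), but fell with library totals (-0.26).

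What set SGT2ox apart from its wild type? Besides Solyc09g061860, a small set of genes was present in one genotype and near 0 in the other. Solyc08g066400 stood at 902.5 ± 24, 1072 ± 99.7 and 618.2 ± 95.3 in SGT2ox at 0, 3 and 24 h and at 0, 1.56 ± 2.69 and 2.85 ± 1.28 in the wild type. Solyc05g015780.1 stood at 369.9 ± 30.4, 995.2 ± 13.9 and 806.7 ± 50.6 in SGT2ox and at 0, 0 and 0.358 ± 0.62 in the wild type. Solyc02g021785.1 went from 305.2 ± 34.8, 256.7 ± 16 and 100.7 ± 14.7 in the wild type to 0.58 ± 1, 0 and 0 in SGT2ox, and Solyc10g009595.1 from 298.7 ± 36.7, 735.5 ± 50.6 and 71.97 ± 15.6 to 0.562 ± 0.974, 0 and 0.723 ± 1.25.

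Between SGT2ox and its wild type 5713 genes differed at 0 h (3130 higher, 2583 lower), 3895 at 3 h (1623 higher, 2272 lower) and 7188 at 24 h (3388 higher, 3800 lower). Most of these differences were small, with a median absolute log2 fold change among called genes of 0.34, 0.34 and 0.38, and 729, 603 and 1011 genes reached 2-fold. At all 3 times 325 genes were higher and 309 lower, where independent lists would hold 34 and 44. The 3 comparisons share an estimate of the spread, so genes with little spread can be called at each time. Independent lists are therefore not the level to be met without lasting differences. With library totals the split became 2054 higher and 4641 lower at 0 h and 2537 higher and 1496 lower at 3 h. When only the 6 libraries of 3 h were fitted, 2559 genes were called.

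SGT1ami was set apart by a like set of genes, but not at the same times. Solyc06g035940 stood at 3625 ± 111 and 1565 ± 36.1 in SGT1ami at 0 h and 3 h, against 5.03 ± 4.53 and 4.5 ± 4.02 in its wild type, and at 2.43 ± 2.44 in the libraries labelled SGT1ami at 24 h. Solyc12g044440 stood at 281.1 ± 40 and 343.7 ± 33 against 0 and 0.323 ± 0.559, and at 0 in the labelled libraries of 24 h. Solyc02g021785.1 was at 0 in all 6 SGT1ami libraries of 0 h and 3 h, against 431 ± 56.5 and 277.7 ± 25.6, and at 291.8 ± 25 in those labelled SGT1ami at 24 h, beside 332 ± 28.3 in the wild type. Solyc10g038185.1 was at 0.525 ± 0.91 and 0 against 253.4 ± 20 and 224.9 ± 12.4, and at 101.8 ± 9.02 against 115.7 ± 9.83 at 24 h. The rule's falls at 24 h were Solyc04g071083.1, at 40.5 ± 16.1 in the labelled libraries against 256 ± 59.8, and Solyc06g035700.1, at 0 against 5.89 ± 1.39. Its rises were Solyc09g075590.1, at 8.09 ± 2.82 against 0, and Solyc03g098060, at 5.66 ± 1.38 against 0. Only Solyc04g071083.1 of these lay above 10 in either group.

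Between SGT1ami and its wild type 4253 genes differed at 0 h (2353 higher, 1900 lower) and 6264 at 3 h (3085 higher, 3179 lower). Between the libraries labelled SGT1ami at 24 h and the wild type 4935 differed (1541 higher, 3394 lower). At least 2-fold were 446, 656 and 254 genes. The median absolute log2 fold change among called genes was 0.29, 0.30 and 0.24. At all 3 times 117 genes were higher and 271 lower, where independent lists would hold 23 and 41, and only 4 and 3 of these were at least 2-fold apart at each time. The shared estimate of the spread limits this comparison too. Opposite calls at 0 h and 24 h also exceeded independent lists, with 630 genes higher at 0 h and lower at 24 h (358) and 257 the other way round (131). With library totals the split became 3604 higher and 2694 lower at 3 h and 3461 higher and 1603 lower at 24 h. Without the libraries labelled SGT1ami at 24 h, a setting chosen after the data were seen, 4329 genes were called at 0 h and 6360 at 3 h.

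**Figure D4:**
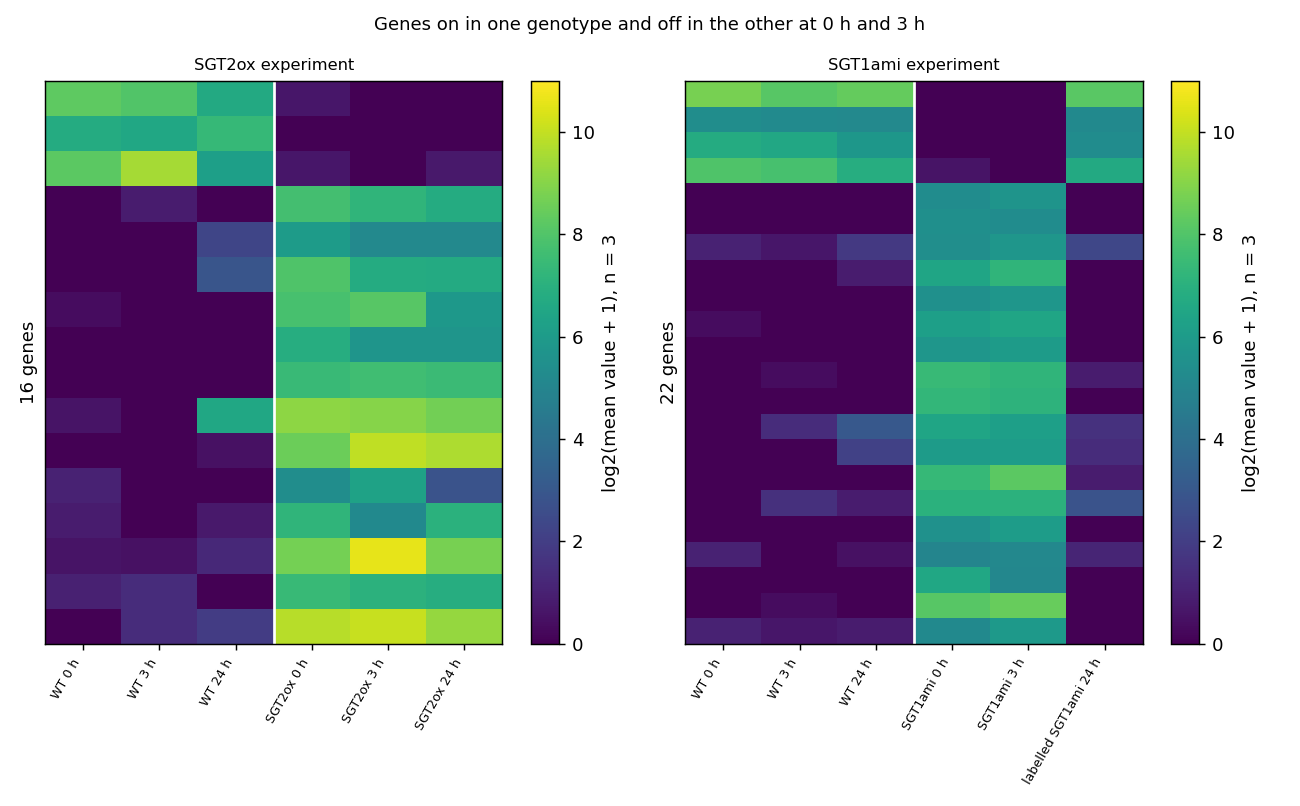
Levels, as log2(mean value + 1) of 3 libraries, of 16 genes in the SGT2ox experiment (left) and 22 in the SGT1ami experiment (right) that were on (mean of at least 30) in one genotype and off (mean of at most 2) in the other at 0 h and at 3 h, limits set after the data were seen. At 24 h 15 of the 16 genes stayed nearer to the earlier SGT2ox level in SGT2ox, 1 of them in the wild type too, and all 22 were nearer to the wild type level in the libraries labelled SGT1ami.

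Did a line respond to time differently from its wild type? In SGT2ox Solyc03g096140 fell from 113.6 ± 14.4 to 1.55 ± 1.34 between 0 h and 3 h while the wild type went from 2.67 ± 0.988 to 13.7 ± 2.86. Solyc08g006280 went from 20.2 ± 10.1 to 61.1 ± 27.3 in SGT2ox and from 142.5 ± 11.7 to 12.7 ± 5.65 in the wild type. Over 24 h Solyc10g019227.1 stayed near its level in SGT2ox (120.6 ± 2.97 and 116.3 ± 7.94) and went from 29.9 ± 3.68 to 0 in the wild type. The change from 0 h differed between SGT2ox and wild type for 4058 genes at 3 h (1546 more positive in the line, 2512 more negative) and for 5225 at 24 h (2250 and 2975). At least 2-fold were 514 and 833 of these differences. With library totals the median difference at 3 h moved to 0.12, and the splits became 3890 and 1332 at 3 h and 3111 and 2239 at 24 h.

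The size of the response was read in genes chosen in the wild type of the other experiment, so that the choice shared no library with the values. At 24 h the 5131 genes that rose at least 2-fold there rose by a median of 1.58 in the wild type of SGT2ox and 1.77 in SGT2ox on the log2 scale, a median difference of 0.14 (bootstrap interval over genes 0.13 to 0.16). The 4388 that fell there changed by -1.36 and -1.50, a difference of -0.16 (-0.17 to -0.14). At 3 h the 2304 rising genes showed a difference of -0.12 (-0.15 to -0.10) and the 1325 falling genes one of 0.07 (0.04 to 0.11). With library totals these medians were 0.20 and -0.09 at 24 h and 0.02 and 0.21 at 3 h. That scaling moved rising and falling genes together, and the median of the rising minus that of the falling genes was -0.19 with it and -0.20 without it at 3 h, and 0.29 and 0.30 at 24 h. These intervals treat genes as independent and leave out the spread between plants.

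In SGT1ami Solyc01g108710 fell from 38.4 ± 7.41 to 1.84 ± 0.0116 between 0 h and 3 h while its wild type went from 15.9 ± 5.65 to 31.9 ± 14.9. Solyc06g007980 differed in its change to 3 h by 0.36 (adjusted p = 2.1e-06, limma), since it was 1.32-fold lower than at 0 h in the wild type and 1.03-fold lower in SGT1ami (log2 fold change -0.04, adjusted p = 0.36, limma). With library totals that change within SGT1ami was -0.24 and passed the test. The change from 0 h differed between SGT1ami and wild type for 4518 genes at 3 h (2010 more positive, 2508 more negative, 516 at least 2-fold). For the libraries labelled SGT1ami at 24 h it differed for 5238 genes (1807 and 3431, 596 at least 2-fold), and Solyc06g035940, Solyc12g044440, Solyc02g021785.1 and Solyc10g038185.1 were among them. With library totals the splits became 2358 and 2243 at 3 h and 3022 and 2052 at 24 h. Among genes that rose at least 2-fold in the other wild type at 24 h (4407 genes), the labelled libraries differed from wild type by a median of -0.12 (-0.14 to -0.11), and among those that fell (4028 genes) by -0.03 (-0.05 to -0.02), or -0.01 with TMM scaling. At 3 h these medians were -0.02 (-0.04 to 0) over 2622 genes and 0.10 (0.08 to 0.13) over 2359. With library totals they were -0.04 and 0.06 at 24 h and 0 and 0.13 at 3 h, and the median of the rising minus that of the falling genes was -0.09 at 24 h and -0.13 at 3 h with either scaling.

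One line is named for more SGT2 and the other for less SGT1, so their differences from wild type were set side by side. Called genes shared their direction more often than not at 0 h and 3 h. Solyc08g066400 was higher and Solyc02g021785.1 lower than wild type in both lines at both times. At 0 h 1192 of the 21851 genes tested in both experiments were called in the same direction and 777 in opposite directions, and at 3 h 1539 and 406. At 24 h, with the libraries labelled SGT1ami, 864 were called in the same and 1471 in opposite directions. Of the genes at least 2-fold apart in both lines, 81 had the same and 33 opposite directions at 0 h, 97 and 26 at 3 h, and 21 and 23 at 24 h. Rises common to both lines numbered 704 at 0 h (325 for independent lists, odds ratio 3.18, p = 1.9e-104, adjusted p = 3.6e-104, two-sided Fisher's exact test) and 632 at 3 h (219, odds ratio 5, p = 6.8e-161, adjusted p = 1.6e-160, same exact test). Opposite calls also exceeded independent lists at 0 h, with 405 genes higher in SGT2ox and lower in SGT1ami (266 for independent lists) and 372 the other way round (271), but not at 3 h, with 151 (226) and 255 (313). Genes higher in SGT2ox and lower in the labelled 24 h libraries numbered 1025 (513 for independent lists, odds ratio 3.07, p = 2.2e-134, adjusted p = 4.5e-134, two-sided Fisher's exact test), and those the other way round 446 (264). At 24 h common falls numbered 730 (585 for independent lists, odds ratio 1.39) and common rises 134 (232). Adjustment was over 68 such tests in 17 pairs of comparisons, and genes are not independent replicates. Across genes r was 0.17, 0.31 and -0.06 and rho 0.10, 0.26 and -0.12 at 0, 3 and 24 h. The lines and their wild types came from separate experiments, so a difference between lines cannot be told apart from one between experiments.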

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

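The tests on marker genes, on the overlap of the SGT1ami differences at 24 h with those at 0 h and 3 h and on scaling, the share of lasting line differences and the counts over other splits of the samples were chosen only after the results had been seen; the tests of a fixed wild type difference and of the time response were written before.

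The libraries labelled SGT1ami at 24 h carried wild type levels of genes that marked SGT1ami at 0 h and 3 h. Of 22 genes on (mean of at least 30) in one genotype and off (at most 2) in the other at both earlier times, 22 were nearer to the wild type state in these libraries, in 65 of 66 single-library comparisons, whereas 15 of the 16 such genes of SGT2ox were nearer to the line state in SGT2ox at 24 h, 1 of them in its wild type too (Solyc04g039670, 91.8 there and 407.6 in SGT2ox, named after its values were seen). An exchange of labels with the wild type is argued against, since 0 of the 22 were in the line state in the wild type libraries of 24 h, and so is the scaling, since the log2 fold change of Solyc06g007980 was -0.11 at the lowest over 5 scalings, against -1.33 at 3 h. That the markers follow the level of SGT1 alone in both lines is argued against for the 3 shared with SGT2ox as a set. All 3, and without Solyc04g039670 the other 2, were in the line state in SGT2ox at 24 h, where Solyc06g007980 stood at 6916, above the 6173 of the labelled libraries. Solyc09g061860 was 32.1-fold higher there than in wild type, so the shared genes could follow SGT2 in SGT2ox and SGT1 in SGT1ami, which was not tested. For the other 19 it cannot be told apart, because Solyc06g007980 stood at 3703 in the wild type of SGT2ox at 3 h, where 2 of them were in the line state, and at 2435 and 2373 in SGT1ami. As a hypothesis these libraries may come from wild type plants. A loss of silencing stays open as well, and the tables do not settle it. The 4935 genes that differed from wild type (254 at least 2-fold, 25 called in the highest other split) cannot decide. No experiment held 2 wild type groups of the same hour, so how far such groups differ is not known. Libraries of the separate experiments that were both labelled wild type differed at 16055 genes at 24 h, which includes any difference between the experiments. The calls shared with SGT1ami at 3 h went the same way for 1753 genes and opposite ways for 504 (22 and 15 among those at least 2-fold in both). Those shared with 0 h went the same way for 760 and opposite ways for 887. The bound set for wild type plants asked for a more even split at 3 h than 1753 against 504, so it was not met.

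The wild types of both experiments differed from each other at more genes than a line from its own wild type. At 0, 3 and 24 h 4267, 4102 and 5319 of 21851 genes were called and at least 2-fold apart, and by a test of the difference itself the change from 0 h differed for 11860 genes at 3 h and 12011 at 24 h. The choice of TMM or the deposited size factors is argued against as the cause, since with TMM on the recovered reads 4288 genes were apart at 0 h. With the deposited factors, each experiment fitted on its own, 729 were apart for SGT2ox and 446 for SGT1ami. Both scalings assume that most genes do not change, and depth was not tested. A fixed difference between the stocks cannot be told apart: 10.2% of the 8841 genes apart at any time (900 genes) were apart the same way at all 3 times, but the bound of 50% set against it was wrong, because the share was 6.4% of 1839 genes for SGT2ox, a fixed genotype, and 0.6% of 1117 for SGT1ami as labelled. Growth, sampling or library conditions that differed between the experiments stay open and were not tested, and no biological explanation was tested, as the labels give both sets the same genotype.

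Both lines differed from wild type more often in the same direction at 0 h and 3 h and more often in opposite directions at 24 h, but among genes at least 2-fold apart in both lines the 24 h excess was absent (21 in the same and 23 in opposite directions). The scaling is argued against, since with library totals 1552 genes were called in opposite directions and 700 in the same direction at 24 h. A line difference that follows the time response was tested as a cause. Across genes the SGT2ox difference at 24 h had a rho of 0.33 with the 24 h change in the other wild type and 0.01 with its 3 h change. For the libraries labelled SGT1ami these were -0.03 and -0.11, so only the SGT2ox difference followed the 24 h change. Removing the time changes of the other experiment moved the rho between lines from -0.12 to -0.09. Whether the time response contributes cannot be told apart, because the remaining rho lies between the bounds set for and against it. The 24 h side rests on the libraries labelled SGT1ami, so wild type plants behind that label stay open here as well.

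The change from 0 h differed between SGT2ox and its wild type for 4058 genes at 3 h and 5225 at 24 h, by a test of the difference itself, and between SGT1ami and its wild type for 4518 genes at 3 h and 5238 at 24 h, the last with the labelled libraries. Of 100 splits of the samples 1, 2, 2 and 1 gave as many genes, the real split included, and the highest of the others called 2477, 7701, 5811 and 4384 genes. No conclusion is drawn from these shares, because splits that left line and wild type whole at either time kept the line difference at that time. The splits with 7701, 5811 and 4384 exchanged line and wild type at the later time, which tests the sum of the line differences at both times, and the highest without them called 3261, 2541 and 1629. That exchange was not drawn for SGT2ox at 3 h, where it called 5491. The splits mixed at both times, 85, 83, 74 and 82 of them, called at most 1, 1, 2 and 3. With replicates this alike, mixing the groups removed nearly all calls, which does not test the difference of the changes apart from the line differences. For the changes of the wild types, 1 of 100 splits gave as many genes as the real 11860 at 3 h, and the highest other called 11570. At 24 h 6 of 100 gave as many as the real 12011 (highest other 12725). The other 5 left the wild types whole at either time and so kept the difference between the experiments, and these shares decide nothing either. The exchange of the wild types at the later time was not drawn and called 16076 and 16801, and the splits mixed at both times, 83 and 82 of them, called at most 2 and 2.

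For comparisons of 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, gave as many genes in each. In the wild type of SGT2ox the real split called 14841 genes at 3 h and 17713 at 24 h, and the highest other 2 and 0. In the wild type of SGT1ami these were 13974 and 18355, and 2 and 0. In SGT2ox they were 14519 and 18164, and 3 and 0, and in SGT1ami as labelled 13853 and 18448, and 0 and 0. Between SGT2ox and its wild type the real split called 5713, 3895 and 7188 genes at 0, 3 and 24 h and the highest other 2, 3 and 3. Between SGT1ami as labelled and its wild type these were 4253, 6264 and 4935, and 2, 4 and 25. Between the wild types, for the 2-fold counts of 4267, 4102 and 5319, the highest others were 2, 2 and 5.

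By the same test of the difference, the change of Solyc09g061860 from 0 h was more positive in SGT2ox than in its wild type by 0.31 at 3 h and 0.26 at 24 h on the log2 scale (adjusted p = 8.1e-05 and 5e-04, limma). In the SGT1ami experiment it was more positive than in wild type by 0.32 at 3 h and by 0.23 in the libraries labelled SGT1ami at 24 h (adjusted p = 5.6e-06 and 0.00044, limma). The change of Solyc06g007980 was more positive than in wild type by 0.36 in SGT1ami at 3 h and by 1.57 in the libraries labelled SGT1ami at 24 h (adjusted p = 2.1e-06 and 1.7e-18, limma).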

How the results depend on the processing

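Scaling by library totals and leaving out the libraries labelled SGT1ami at 24 h were chosen only after the results had been seen; the other settings were planned.

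The 18 counts of called genes stayed within 1.5 times of the reported value with TMM, edgeR, DESeq2, a pseudocount of 8, no filter, a filter of 50, one fit of 36 libraries, library totals and each library left out. With single libraries left out, 4603 to 4836, 3004 to 3360 and 6292 to 6481 genes differed between SGT2ox and wild type at 0, 3 and 24 h, and 3488 to 3790, 5256 to 5441 and 4185 to 4288 between SGT1ami as labelled and wild type. A 2-fold threshold lowered all 18 by its construction, to 5174 and 8730 (wild type of SGT2ox at 3 h and 24 h), 3708 and 9772 (wild type of SGT1ami), 4998 and 9436 (SGT2ox), 3376 and 9751 (SGT1ami as labelled), 729, 603 and 1011 (SGT2ox against wild type at 0, 3 and 24 h), 446, 656 and 254 (SGT1ami as labelled), 514 and 833 (difference of changes, SGT2ox) and 516 and 596 (SGT1ami as labelled). Fitting only the groups compared, with fewer libraries to estimate the spread, gave 2559 genes for SGT2ox against wild type at 3 h and 254 called in opposite directions in the lines at 3 h. The rho between lines was 0.21 at 3 h without a filter, and at 24 h -0.08 without a filter and -0.14 with a filter of 50; the cause was not tested. With library totals the 24 h change of Solyc09g061860 reversed to -0.58 in the wild type of SGT1ami and -0.26 in the libraries labelled SGT1ami, where that scaling moved the median gene by -0.58 and -0.50. The median difference of the response reversed to 0.02 in rising genes of SGT2ox at 3 h and to 0.06 in falling genes of the libraries labelled SGT1ami at 24 h, but rising and falling genes moved together and the median of the rising minus that of the falling genes stayed at -0.19 (-0.20 as reported) and -0.09. This scaling also ended or added 4 calls of the target identifiers, and the fit of 36 libraries added 1 (Solyc06g007980 in SGT2ox at 0 h, 0.09). Of the values of single identifiers with a library left out, 595 kept their call and 5 lost it, all of them targets in the libraries labelled SGT1ami at 24 h. The filter of 50 left 3 identifiers untested.

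With the replicate number as a block, 5622, 3830 and 7137 genes differed between SGT2ox and wild type, 5548, 3740 and 7026 of them also without it. No count moved by over 1.5 times, and no call of an identifier run under the settings changed. Solyc08g006280, Solyc12g044440 and Solyc10g038185.1 were not run under any alternative setting for the differences of changes in which they are named. Samples of the same number did not deviate together (correlations of -0.05 to 0.07 over 45 pairs per experiment), and 6 of 18 samples in each experiment were closest to their own number, so the numbers are not read as pairs. Without the libraries labelled SGT1ami at 24 h, 14190 and 18442 genes changed in the wild type of SGT1ami at 3 h and 24 h and 14010 in SGT1ami at 3 h, 4329 and 6360 differed between them at 0 h and 3 h, and the change to 3 h differed for 4604. The planned gene list tests were not run under any setting. On counts simulated at the depth and spread of these libraries, with 40 genes changed at each fold, 7.7% of genes changed 1.1-fold, 57.9% changed 1.25-fold and 95% changed 4-fold were recovered for SGT2ox against wild type at 0 h. These shares do not carry over to the data, where far more genes were called, and the part of depth alone was not tested.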

Other observations

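All tests in this part were chosen only after the results had been seen.

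In wild type leaves fewer genes changed in opposite directions at 3 h and at 24 h than independent lists would share. The 2 genes named above as falls at 3 h stood higher at 24 h than at 3 h. Solyc12g009880.1 fell from 724.4 ± 49.3 to 43.8 ± 18.8 at 3 h in the wild type of SGT2ox and stood at 223.5 ± 39.4 at 24 h, and in the wild type of SGT1ami it fell from 674.8 ± 21.7 to 35.7 ± 5.33 and stood at 695.6 ± 18.2 (mean ± SD, n = 3). Solyc01g096790 fell to 3.25 ± 3.05 and 1.29 ± 1.12 at 3 h and stood at 47.2 ± 7.68 and 31.5 ± 8.44 at 24 h. Times were compared across experiments, so that no library was shared. The 3 h change in the wild type of SGT2ox and the 24 h change in that of SGT1ami were called in the same direction for 6863 genes and in opposite directions for 5662 (3737 common rises, 3284 for independent lists). Higher at 3 h and lower at 24 h were 2933 genes (3109 for independent lists), and the other way round 2729 (2946). The 3 h change in the wild type of SGT1ami and the 24 h change in that of SGT2ox shared direction for 7233 genes and were opposite for 4443 (3858 common rises, 2725 for independent lists). Here 2056 were higher at 3 h and lower at 24 h (2735 for independent lists), and 2387 the other way round (2802). At least 2-fold in both were 1612 and 1787 genes in the same direction and 1111 and 438 in opposite directions.

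Genes with very large line differences were partly the same in both lines. At least 4-fold higher than wild type at 0 h and at 3 h were 34 genes in SGT2ox and 34 in SGT1ami, of which 15 were common (0.053 for independent lists, p = 3.6e-35, two-sided Fisher's exact test), and at least 4-fold lower were 31 and 21, of which 7 were common (0.03 for independent lists, p = 6.4e-16, same exact test). In opposite directions 1 and 1 were found. The 22 common genes include Solyc08g066400 and Solyc02g021785.1. A candidate explanation is a background that both lines share and their wild types lack, which needs such an excess of common genes; an effect of both transgenes on the same genes was not tested.

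These genes also lay closer together in the order of identifiers than genes drawn at random from those tested. In SGT2ox 12 of 65 had another within 10 places (random lists had a median of 4 and at most 17, one-sided permutation p = 0.006, adjusted p = 0.006), and in SGT1ami 15 of 55 (median of 2, at most 13, one-sided permutation p = 1e-04, the smallest that 10000 permutations can give, adjusted p = 2e-04). The order is that of the identifiers, and no coordinates were used. As a hypothesis, stretches of the genome may differ between lines and wild types, and neighbours that are regulated together or share reads could give the same excess.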
